A study of Mus musculus and Homo sapiens with 31 samples.

How the data were processed

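RNA sequencing of 11 mouse T-cell lymphomas and 14 human samples was examined. Whole-genome bisulfite sequencing of 6 mouse lymphomas is part of the same series and was not analysed here, since only the expression tables were in hand. Both expression tables hold FPKM values (fragments scaled to the length of the gene and the size of the library), as deposited by the authors. STAR and DESeq2 are the expression tools named per the submitters' processing notes, which also name the builds mm10 and hg19; which program made the FPKM values is not stated. Total RNA was taken with Trizol and sequenced as paired ends on a NovaSeq6000, per the labels.

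The mouse table has 34245 rows, of which 1 without a gene identifier was left out. The human table has 35858 rows, of which 38 without an identifier, holding 0.0846% of the summed FPKM, were left out. A symbol with more than 1 row (36 in mouse, 46 in human) was represented in the lists by the row with the highest mean. All columns were mapped to samples by their titles. No value is 0: low values lie on steps of 1 read per gene, and a gene without reads sits at 0.9 of a step. The step size gave the implied depth of each library, and at least 94.0% of the low values in every mouse library and 97.3% in every human library were whole numbers of reads within a tolerance of 0.02. Read numbers and limits from them cover counting error only, and neither molecular identifiers nor the strand used for counting is stated, so overlapping and antisense genes are uncertain.

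Mouse gene coordinates in the deposited table overlapped the GRCm38 gene of the same symbol for 99.8% of 24544 symbols. Human coordinates overlapped the GRCh38 gene of the same identifier for 99.8% of 35225 identifiers, although the notes name hg19. Whether each human value belongs to its row's gene was then tested with tracers, which are 2934 genes with FPKM of at least 5 in every mouse library and a human row of the same name. A tracer was in place when its human mean reached 1 FPKM. Only 557 tracers (19%) were in place. They clustered: the longest run of neighbouring tracers in place was 71, against 13 in 1000 shuffles within chromosomes. The 6 stretches with at least 10 tracers in place in a row, called spans, hold 1353 rows. Inside them the mean FPKM of genes that were not tracers followed the mouse mean across 447 genes with Spearman rho 0.75, against 0.09 across 12707 genes outside; genes are not independent replicates. Changes of human genes are reported here from the spans alone, and values of other human rows are not read as those of the named gene.

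Expression was compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with values as deposited, genes with a mean of at least 1 FPKM over all libraries of the species, lmFit and eBayes with a trend, and two-sided tests. A Benjamini-Hochberg adjusted p below 0.05 over all genes tested was the threshold. The mouse fit used all 11 libraries and gave D/D against wild type, CI/CI against wild type and CI/CI against D/D. The human fit used all 14 libraries and gave lymphoma against the mean of normal CD4 and CD8 T cells, and CD8 against CD4. A log2 fold change here is on the log2(FPKM + 1) scale, which understates low genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the plots.

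Gene lists were tested with camera at an inter-gene correlation of 0.01, for lists with at least 5 measured members, and again with an estimated correlation and with fry. There were 30 lists: cell programmes, other cell types and handling of tissue. In mouse 21 had enough members; in human only 14 of 471 list members lay in the spans and 0 lists had enough, so no human list was tested. Adjusted p values of lists are over all lists tested in a comparison. Counts adjusted over the list alone are given beside counts over all genes. Genes were named by a rule: Dnmt3b, Dnmt1, Dnmt3a, Myc and Met; the 8 largest rises and 8 largest falls past the threshold whose groups do not overlap, without predicted genes, clones, pseudogenes, small RNAs, mitochondrial genes or antigen receptor segments; where fewer than 3 passed, also the 3 smallest p, named as not past the threshold; list members past the threshold, up to 4, or otherwise the 2 with the highest mean; and mouse sex-linked genes. Any other gene is named as chosen after its values were seen. Some items that the rule or a list would name are not reported here.

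Groups, comparisons, the test, its threshold, the lists and the naming rule were fixed before the data were examined, as were these alternatives: a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, upper-quartile scaling, quantile normalization, eBayes without trend or robust, arrayWeights, replicate numbers as a block, fits of the compared groups alone, pooled or separate normal T cells, human tumours of either title series, and each mouse library of the compared genotypes and each normal human library left out in turn. Chosen after the data were seen were the spans, the division of human libraries at 100 M reads (M, mega), depth class as a block, leaving out both mouse libraries numbered 4, the replicate block with an estimated correlation and, for gene counts and named genes but not for lists, leaving out each library of the genotype not compared. Replicate numbers were treated as pairs where at least 3 same-number pairs existed and every pair deviated alike, with a Pearson r across genes over 0.1. This held for CI/CI and wild type (0.16, 0.41 and 0.71) and not for CI/CI and D/D (-0.15, -0.14 and 0.02). D/D and wild type share only 2 numbers (0.46 and 0.17), too few for the rule. The labels do not state a pairing. CI/CI and wild-type libraries of unlike number ran from -0.48 (wild-type replicate 3, CI/CI replicate 4) to 0.34 (wild-type replicate 2, CI/CI replicate 1), so the pairing is uncertain. On simulated data with 200 changed genes the same fit recovered 28.4% of 2-fold, 83.1% of 4-fold and 97.1% of 8-fold changes for D/D against wild type, with 10 false calls. For CI/CI against wild type it recovered 36.8%, 91.8% and 100%, and for lymphoma against normal human T cells 67.1%, 97.3% and 98.2%. The human rates cover 3146 rows and not the span genes alone. Noise was drawn independently for each gene, while real libraries deviated together across genes, so these rates do not tell how many real changes were missed.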

Results

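Gene expression was measured by RNA sequencing in mouse T-cell lymphomas driven by MYC and in human peripheral T-cell lymphoma. The mouse tumours came from lymph nodes of FVB mice at terminal illness and comprised 3 Dnmt3b+/+ (wild type, replicates 2, 3 and 4), 3 Dnmt3b D/D and 5 Dnmt3b CI/CI tumours. Dnmt3b encodes a DNA methyltransferase that places methyl groups on unmethylated DNA. Sample titles call D/D a knock-out and CI/CI a knock-in, and the labels say no more about either allele. The study states triplicates for RNA, while 5 CI/CI libraries were deposited; each library is a separate sample. The human samples were 10 peripheral T-cell lymphomas (hPTCL) from lymph nodes and, from blood, 2 normal CD4 and 2 normal CD8 T-cell samples.

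The implied depth was 42.2, 36.5 and 34.0 M reads (M, mega) in wild-type replicates 2 to 4, and 37.2, 34.4 and 43.8 M in D/D replicates 1 to 3. In CI/CI replicates 1 to 5 it was 30.8, 40.5, 40.2, 28.4 and 32.3 M. CD4 replicates 1 and 2 had 112.2 and 19.2 M, and CD8 replicates 1 and 2 had 112.1 and 26.4 M. In hPTCL replicates 1 to 10 the depth was 25, 134.2, 41.8, 110.0, 30.7, 21.8, 26.0, 34.3, 42.5 and 31.4 M. The hPTCL numbers follow the order of the samples in the series and are not the numbers in the sample titles. Mouse libraries held 9024 to 10550 genes with at least 1 FPKM and human libraries 2622 to 3377. Pearson r between libraries of a group, across genes, was 0.88 to 0.92 in wild type, 0.874 to 0.939 in D/D, 0.768 to 0.96 in CI/CI and 0.597 to 0.904 in hPTCL.

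Dnmt3b, the gene altered in these mice (chromosome 2, 153649450 to 153687730), was expressed in all 3 genotypes. Its level was 1.90, 2.33 and 2.13 FPKM in the wild-type tumours, 2.26, 1.49 and 4.36 FPKM in D/D and 4.66, 5.11, 4.30, 8.51 and 4.55 FPKM in CI/CI. The CI/CI mean of 5.43 ± 1.75 FPKM (SD, n = 5) lay above the wild-type mean of 2.12 ± 0.216 FPKM (SD, n = 3) in every library, a log2 fold change of 1.01 (SE 0.26) that did not pass in limma (adjusted p = 0.262; 0.0137 to 0.802 over the alternatives). Adjusted over the list of DNA methylation genes alone, Dnmt3b was the 1 member that passed in CI/CI. D/D differed from wild type by 0.18 (SE 0.29), less than the spread of the D/D tumours. A gene-level value does not check a deleted exon or a point change. The maintenance methyltransferase Dnmt1 was at 58.3 ± 20.1, 65.7 ± 22.7 and 63.9 ± 18.2 FPKM in wild type, D/D and CI/CI, and Dnmt3a at 4.12 ± 1.55, 5.28 ± 1.08 and 4.55 ± 1.35 FPKM (SD, n = 3, 3 and 5). Mouse Myc was low in all 3 genotypes, at 1.54 ± 0.621, 1.11 ± 1.43 and 0.636 ± 0.398 FPKM; any reads from an introduced MYC gene are not separated in these values. Met, encoding a receptor tyrosine kinase, was near 0.0205, 0.0245 and 0.0854 FPKM, below the level tested. None of these genes passed the threshold in any mouse comparison in limma.

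In D/D tumours, set against wild type to ask what the D allele changes, the uncharacterised gene AI506816 rose, as did a T-cell receptor segment. AI506816 (chromosome 5, 23698296 to 23712667) reached 56.7 ± 23.4 FPKM in D/D (SD, n = 3) from 1.26 ± 1.07 FPKM in wild type (SD, n = 3), a log2 fold change of 4.73 (SE 0.58, adjusted p = 0.0263 in limma). The T-cell receptor joining segment Trbj2-1, a piece of the receptor gene that each T-cell clone keeps or loses as it rearranges, had 1 read over the 3 wild-type libraries and 91.1 ± 14.6 FPKM in D/D (chromosome 6, 41542754 to 41542803; log2 fold change 5.93, SE 0.55, adjusted p = 0.00307 in limma). The transcript 2700081O15Rik (chromosome 19, 7417625 to 7425904) fell by 1.71 on the log2 scale, from 4.48 ± 0.781 to 0.672 ± 0.267 FPKM (adjusted p = 0.0462 in limma). Its fall was not particular to D/D: every CI/CI library lay below every wild-type one, at 1.48 ± 0.527 FPKM (SD, n = 5). In CI/CI it did not pass with all libraries, but did without D/D replicate 2 (log2 fold change -1.155, adjusted p = 0.0464 in limma). Like Trbj2-1, the receptor segment Trbc1 was low in wild type, without passing in limma. Its level was 2.07 ± 1.31 FPKM in wild type, 424.5 ± 127.5 FPKM in D/D and 115 ± 74.0 FPKM in CI/CI (SD, n = 3, 3 and 5). In CI/CI replicate 5 it was 1.94 FPKM. Whether the wild-type clones lost these segments by rearrangement, apart from any effect of an allele, was not tested. Trbj2-1, Trbc1 and 2700081O15Rik were chosen after their values were seen.

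These were the 2 raised and 1 lowered of 10198 genes tested in D/D, with 433 genes at an unadjusted p under 0.05. Of genes not past the threshold, the smallest p went to Rasgef1a, the chemokine receptor Cxcr3 and the interleukin receptor chain Il2rb, all higher in D/D, and to Pdlim4, Trf and Plaur, all lower (adjusted p = 0.132 in limma). Cxcr3 was at 34.3 ± 9.20 FPKM in D/D and 3.33 ± 2.52 FPKM in wild type. Il2rb was at 75.6 ± 24.5 FPKM against 20.8 ± 0.854 FPKM. The count was 58 without D/D replicate 2, 9 without CI/CI replicate 5 and 8 without wild-type replicate 2. It was 1 without any of wild-type replicate 4, D/D replicates 1 and 3 or CI/CI replicates 1 and 3. AI506816 lost its call without wild-type replicate 3 (adjusted p = 0.0713) or 4 (0.0874), D/D replicate 1 (0.0512) or 3 (0.110), or CI/CI replicate 1 (0.0577) or 3 (0.0547); over all alternatives its adjusted p was 0.00242 to 0.186. 2700081O15Rik lost it without any library but D/D replicate 2 and CI/CI replicates 4 and 5, and with replicate numbers as a block (adjusted p = 0.239; 0.00814 to 0.278 over the alternatives).

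Of the 21 gene lists tested in D/D, cytotoxic genes were higher and neutrophil genes lower. All 9 cytotoxic genes measured were higher in D/D, with a median log2 fold change of 1.74 (camera adjusted p = 2.2e-07; adjusted p = 0.197 with an estimated correlation). Gzma, the protease granzyme A of killer cells, had 63.2 ± 50.6 FPKM in D/D and 11.5 ± 17.3 FPKM in wild type. Ctsw had 18.4 ± 10.9 against 5.04 ± 4.06 FPKM. Adjusted over the list alone 4 cytotoxic genes passed, Ctsw, Eomes, Nkg7 and Tbx21, chosen after their values were seen, and 0 members passed over all genes in limma. The groups overlapped for all 4: D/D replicate 2 lay within the wild-type range for Tbx21 (0.980 FPKM), Nkg7 (2.19 FPKM) and Ctsw (7.99 FPKM), and Eomes was at 10.7 FPKM in wild-type replicate 2 and 6.10 FPKM in D/D replicate 3. Without D/D replicate 2, Tbx21 passed over all genes (adjusted p = 0.0122 in limma; 0.0122 to 1 over the alternatives). Cd8a (54.5 ± 31.2 against 17.2 ± 14.1 FPKM) and Cd8b1 (99.0 ± 62.8 against 62.6 ± 35.3 FPKM) were higher in D/D as well without passing (adjusted p = 0.979 for both in limma), and were chosen after their values were seen. All 8 neutrophil genes were lower, with a median of -1.04 (camera adjusted p = 0.00889; adjusted p = 0.595 with an estimated correlation). The call was lost without wild-type replicate 2 (0.360) or D/D replicate 3 (0.120), and its adjusted p was 3.0e-09 to 0.360 over the alternatives at the preset correlation. S100a9, a calcium-binding protein abundant in neutrophils, had 1.03 ± 0.837 FPKM in D/D and 13.8 ± 18.4 FPKM in wild type, so that the wild-type spread exceeded its mean. The other 19 lists had adjusted p of 0.213 to 0.804. The number of lists past the threshold was 4 without wild-type replicate 4, D/D replicate 1 or D/D replicate 2, and 1 without D/D replicate 3.

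**Figure D1:**
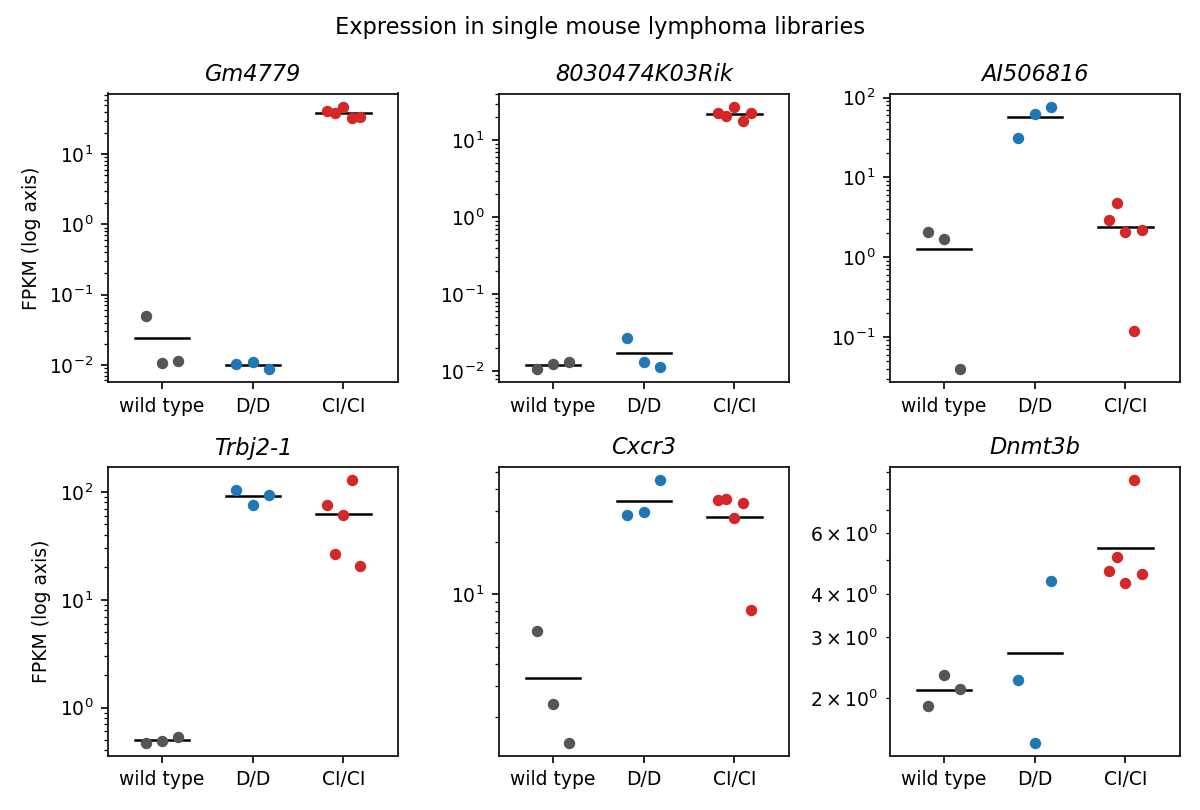
Expression of 6 genes in each mouse lymphoma library (points, FPKM on a log axis; black lines, group means) by Dnmt3b genotype. Gm4779 and 8030474K03Rik lie at 17.8 FPKM or more in the 5 CI/CI libraries and at 0.0501 FPKM or less in the other 6.

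In CI/CI tumours, compared with wild type for what the CI allele changes, a pair of neighbouring X-linked transcripts rose from almost no reads. Gm4779 (X chromosome, 101790053 to 101794423) was at 38.9 ± 6.06 FPKM in CI/CI (SD, n = 5) and 0.0239 ± 0.0227 FPKM in wild type (SD, n = 3), with a log2 fold change of 5.27 (SE 0.15, adjusted p = 9.8e-09 in limma). 8030474K03Rik, which starts 232 bp past its end (101794656 to 101798642), was at 22.3 ± 3.47 FPKM in CI/CI and had 0 reads in wild type. Measured against a limit of 3 reads in a library, it was at least 505-fold higher (log2 fold change 4.51, SE 0.15, adjusted p = 2.9e-08 in limma). Trbj2-1 rose too, to 62.7 ± 43.8 FPKM (log2 fold change 5.11, SE 0.49, adjusted p = 0.0015 in limma). These 3 genes, chosen after their values were seen, were all that passed of 10198.

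At an unadjusted p under 0.05 there were 721 genes for CI/CI against wild type. Those with the smallest p that did not pass were Myadm, Cxcr3 and Slc26a10 on the higher side and Sox4, Cd163l1 and Nck2 on the lower (adjusted p of 0.0742 to 0.105 in limma). Sox4, a transcription factor of immature lymphocytes, was at 15.3 ± 1.96 FPKM in CI/CI and 43.4 ± 13.2 FPKM in wild type. Cxcr3 was at 27.6 ± 11.3 FPKM against 3.33 ± 2.52 FPKM. Replicate numbers as a block paired CI/CI and wild-type libraries, a pairing that the labels do not state. With it 21 genes passed, 11 higher, the receptor segment Trbc1 included (log2 fold change 5.71, adjusted p = 0.00353 in limma), and 10 lower. Cxcr3 (log2 fold change 3.10, adjusted p = 0.0327 in limma; 0.00485 to 0.539 over the alternatives) and Sox4 (-1.47, adjusted p = 0.0434; 0.000827 to 0.282) were among them. The count was 66 without D/D replicate 2, 35 without wild-type replicate 3, 6 without CI/CI replicate 5 and 5 without wild-type replicate 2.

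T-cell identity genes, which encode the receptor complex and the factors that keep T-cell fate, were lower in CI/CI. Of 21 measured, 16 were lower, with a median log2 fold change of -0.31 (camera adjusted p = 1.5e-05; adjusted p = 0.0308 with an estimated correlation). The call held with the replicate block (adjusted p = 0.00171) but not with the block and an estimated correlation together (adjusted p = 0.410). Tcf7, a transcription factor of naive T cells, was at 198 ± 37.5 FPKM in CI/CI and 366 ± 90.6 FPKM in wild type, a log2 fold change of -0.88 (SE 0.23). Lck, the kinase that starts receptor signalling, differed by -0.30 (SE 0.21), within the spread. Members that passed adjusted over the list alone included Cd27, Gata3, Lef1 and Tcf7, chosen after their values were seen, and 0 passed over all genes in limma. The list of p53 targets and cell cycle inhibitors was also lower, in 13 of 16 genes with a median of -0.21 (camera adjusted p = 0.00387; adjusted p = 0.114 with an estimated correlation). Its most abundant members, Bax (-0.18, SE 0.33) and Trp53 (-0.03, SE 0.25), did not differ beyond the spread. The other 19 lists had adjusted p of 0.0552 to 0.898, the lowest for MYC targets, with 23 of 26 higher, and for JAK-STAT and survival genes.

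MYC targets and JAK-STAT genes, with 0 calls over all genes in limma, passed in CI/CI in some alternatives only. Without both libraries numbered 4 the adjusted p was 0.000136 for MYC targets (0.000136 to 0.241 over the alternatives) and 0.0223 for JAK-STAT and survival genes, lower in 14 of 19 (0.00162 to 0.196); with an estimated correlation on all libraries both had an adjusted p of 0.647. MYC targets also passed without wild-type replicate 4 (0.0240), CI/CI replicate 1 (0.0432) or CI/CI replicate 4 (0.0104), and JAK-STAT genes without wild-type replicate 2 (0.0189), D/D replicate 2 (0.0242), CI/CI replicate 1 (0.0496) or CI/CI replicate 4 (0.0281). Neutrophil genes were higher in 7 of 8 without passing (0.176). They passed with the replicate block (0.00421), but not with the block and an estimated correlation together (adjusted p = 0.843), and they passed without wild-type replicate 2 (0.000369) or CI/CI replicate 5 (0.00301; 0.000369 to 0.771 over the alternatives). Lists of other cell types with fewer than 5 measured genes were not tested, and some moved too. Red cell genes were lower in 3 of 3, with a median of -2.69: Hba-a1, a haemoglobin chain, was at 25.4 ± 25 FPKM in CI/CI and 110.5 ± 23.0 FPKM in wild type, and Hba-a1, Hbb-bs and Alas2, the last chosen after its values were seen, passed adjusted over the list alone. Endothelial genes were higher in 4 of 4, with a median of 0.91, led by Plvap (2.24, SE 1.02), and Epcam was higher by 1.16 (SE 0.39); of these Epcam alone passed adjusted over its list, and 0 passed over all genes in limma. The number of lists past the threshold was 6 without wild-type replicate 2, 5 without CI/CI replicate 4 and 4 without CI/CI replicate 1.

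**Figure D2:**
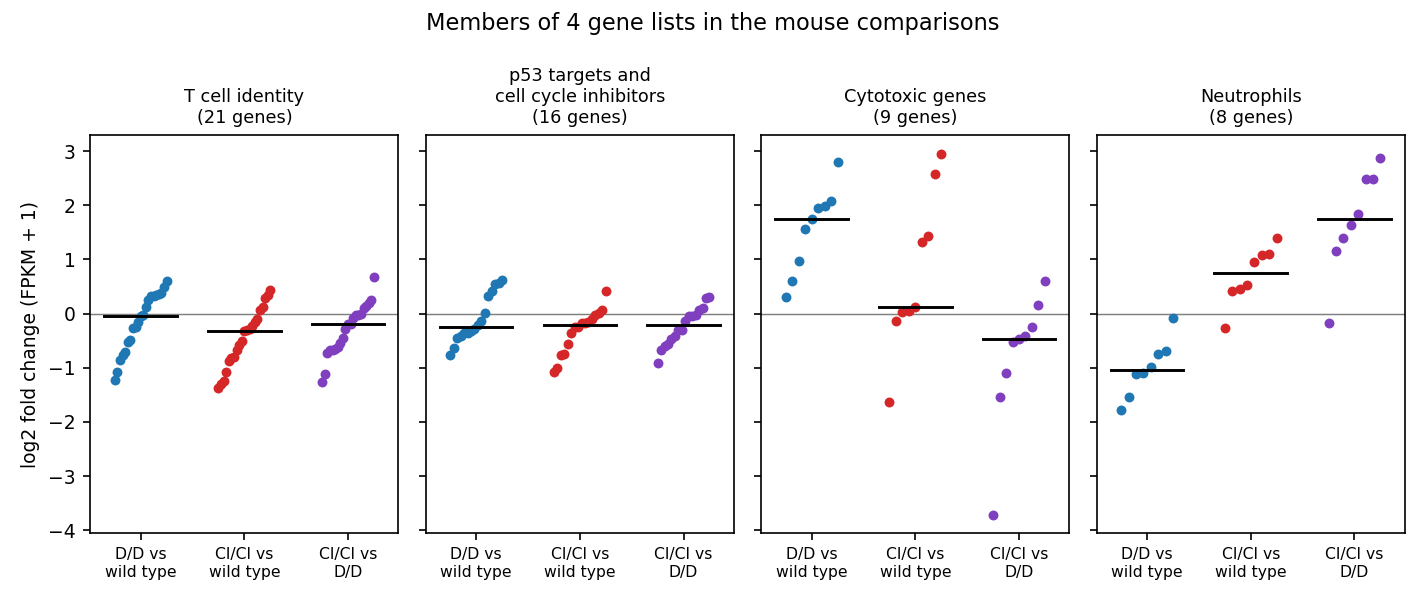
Log2 fold change on the log2(FPKM + 1) scale of each measured member of 4 gene lists (points; black lines, medians) in 3 mouse comparisons. All 9 cytotoxic genes lie above 0 and all 8 neutrophil genes below 0 in D/D against wild type, and 16 of 21 T-cell identity genes lie below 0 in CI/CI against wild type.

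CI/CI and D/D tumours were set against each other to test whether the alleles differ. Gm4779 and 8030474K03Rik were on in CI/CI alone, AI506816 was high in D/D alone, and Eomes, a factor of killer T cells, was nearly absent in CI/CI. Gm4779 had 0 reads in D/D and, against a limit of 3 reads in a library, was at least 1060-fold higher in CI/CI (log2 fold change 5.29, SE 0.15, adjusted p = 9.4e-09 in limma). 8030474K03Rik was higher by 4.50 (SE 0.15, adjusted p = 3.0e-08 in limma). AI506816 was lower by a log2 fold change of -4.17 (SE 0.52, adjusted p = 0.0199 in limma), at 2.39 ± 1.66 FPKM in CI/CI (SD, n = 5). Eomes did not pass, with 0.195 ± 0.0902 FPKM in CI/CI and 17.4 ± 11.6 FPKM in D/D (adjusted p = 0.0832 in limma). Itgb4 and Sox4 were also lower without passing, and Lyl1, Prss57 and Kctd15 higher (adjusted p of 0.0507 to 0.114). In all 2 genes were higher and 1 lower of 10198, with 547 at an unadjusted p under 0.05.

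With replicate numbers as a block, although the rule for pairs was not met, the CI/CI and D/D tumours differed in 12 genes. The count was 19 without CI/CI replicate 1, 16 without wild-type replicate 2, 10 without D/D replicate 2 and 6 without wild-type replicate 3. AI506816 lost its call without D/D replicate 2 (adjusted p = 0.0526) or 3 (0.0784), or CI/CI replicate 3 (0.0892) or 5 (0.0676); over all alternatives its adjusted p was 0.00119 to 0.223. Neutrophil genes were higher in CI/CI than in D/D, in 7 of 8 members with a median log2 fold change of 1.74 (camera adjusted p = 7.3e-06; adjusted p = 0.451 with an estimated correlation). S100a9 was at 33.3 ± 35.7 FPKM in CI/CI, more spread than its mean, against 1.03 ± 0.837 FPKM in D/D. Adjusted over the list alone 5 neutrophil genes passed, Camp, Elane, Ltf, Mpo and Prtn3, chosen after their values were seen, and 0 over all genes in limma. CI/CI replicate 5 lay within the D/D range for Mpo (0.118 FPKM), Elane (0.0630 FPKM) and Prtn3 (0.107 FPKM). For Camp and Ltf the groups did not overlap. S100a8, also chosen after its values were seen, was at 0.0457 FPKM in CI/CI replicate 4, below every D/D tumour. Cytotoxic genes were lower in 7 of 9, with a median of -0.48 (camera adjusted p = 0.00265, and 0.451 with an estimated correlation). They lost the call with the replicate block (0.103) or without D/D replicate 1 (0.495), with 4.6e-08 to 0.495 over the alternatives. Against wild type the list did not pass in CI/CI, but Gzma (2.95), Tbx21 (2.58), Nkg7 (1.42) and Ctsw (1.32) were higher there too. Eomes was lower (-1.63), and the other members differed by -0.14 to 0.12. The T-cell subset markers Cd8b1 (11.9 ± 7.26 FPKM in CI/CI, 99.0 ± 62.8 in D/D, adjusted p = 0.298 in limma) and Cd8a (9.11 ± 3.87 against 54.5 ± 31.2, adjusted p = 0.307) were lower too without passing, while Cd4 was at 34.4 ± 12.9 against 21.3 ± 22.5 FPKM; these 3 were chosen after their values were seen. T-cell identity genes were lower in 16 of 21, with a median of -0.20 (camera adjusted p = 0.00338; adjusted p = 0.218 with an estimated correlation), and lost the call without D/D replicate 2 (0.0584) or CI/CI replicate 5 (0.0651; 0.000156 to 0.0651 over the alternatives).

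The mutants shared 1 gene that changed the same way against wild type, the receptor segment Trbj2-1. Independent lists would share 0.000588, a value that leaves out the shared wild-type libraries. Across 10198 genes the log2 fold changes of D/D and CI/CI had a Pearson r of 0.57 and a covariance of 0.116. Sharing the same 3 wild-type libraries gives a like correlation by itself: draws of libraries into groups of these sizes gave a median r of 0.596, and a median covariance of 0.085 with an upper limit of 0.211 over the draws. The shared count was 25 without D/D replicate 2, 4 without CI/CI replicate 5, and 2 without wild-type replicate 2 or 3 or with the replicate block.

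Human values could be read for a part of the genome only. The row named GAPDH, an abundant glycolysis gene, lies outside the spans and stood at 0.009 ± 0.004 FPKM in hPTCL (SD, n = 10). Only 19% of 2934 genes strong in every mouse tumour reached 1 FPKM in the human table. Genes in 6 spans, on chromosomes 5, 6, 9, 11, 18 and 19, had values in order: EEF2, a translation factor, stood at 287 ± 79.4 FPKM in hPTCL. Rows named DNMT3B, DNMT1, DNMT3A, MYC, MET, CD4, CD8A and CD8B lie outside the spans, so nothing is reported for these genes. Of 3146 human rows with a mean of at least 1 FPKM, 487 lie in the spans.

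Human lymphomas, compared with normal blood T cells for what marks the tumour, had more CCL19, C3 and UHRF1 transcript and less MYLIP. CCL19, a chemokine that draws T cells into lymph nodes (chromosome 9, 34689567 to 34691277), was at 194 ± 242 FPKM in hPTCL (SD, n = 10) and 0.834 ± 0.967 FPKM in normal T cells (SD, n = 4), a log2 fold change of 5.88 (SE 1.01, adjusted p = 0.00118 in limma). Complement C3 (chromosome 19, 6677704 to 6730562) rose from 0.114 ± 0.122 to 31.6 ± 37.7 FPKM. UHRF1, which guides DNMT1 to replicated DNA and is high in dividing cells (chromosome 19, 4903080 to 4962154), rose from 0.748 ± 0.246 to 5.75 ± 3.26 FPKM, a log2 fold change of 1.82 (SE 0.33, adjusted p = 0.00153 in limma). MYLIP, a ubiquitin ligase (chromosome 6, 16129125 to 16148248), fell from 36.1 ± 7.38 to 4.14 ± 2.29 FPKM, a log2 fold change of -2.99 (SE 0.38, adjusted p = 0.000187 in limma). The tumours came from lymph nodes and the normal cells from blood, so tissue and disease are not separated.

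Among span genes 132 rose and 36 fell of 487 in hPTCL, with 223 at an unadjusted p under 0.05. Among genes whose groups did not overlap, the other largest rises had log2 fold changes of 2.62 to 3.53. They were IFITM3, EBI3, C7, IL33 and BLOC1S5-TXNDC5 and TXNDC5, a pair that overlaps on the chromosome. Other large falls were those of PTGER4, TUBB2A, RICTOR, SH2D3A, CHMP1B-AS1 (an antisense transcript) and FAM8A1, with log2 fold changes of -2.05 to -1.19. UHRF2 fell, by a log2 fold change of -0.81 (SE 0.17, adjusted p = 0.00321 in limma). The chemokine CCL21 (5.77, adjusted p = 0.00916), MBD3 (0.95, adjusted p = 0.0324) and RPS6 (-0.90, adjusted p = 0.0321) passed with overlapping groups, while IL7R, JAK2, CDKN2A and PAX5 did not pass (adjusted p of 0.0729 to 0.396). The median log2 fold change of the span genes was 0.324. With upper-quartile scaling the median was 0.007 and 74 genes were higher and 85 lower; with quantile normalization 72 were higher and 95 lower.

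The balance of rises and falls in hPTCL therefore depends on the scaling, while every gene named here as past the threshold passed under each scaling except RPS6, under quantile normalization, and MBD3, under upper-quartile scaling (adjusted p = 0.0793) and quantile normalization (0.0520). The count was 91 without CD4 replicate 1, 108 without CD4 replicate 2 and 74 without CD8 replicate 2. SH2D3A lost its call without CD4 replicate 1 (adjusted p = 0.0552) or CD8 replicate 2 (0.0578), with 0.000357 to 0.262 over its alternatives. RPS6 lost it without CD4 replicate 1 (0.153), CD8 replicate 1 (0.0832) or CD8 replicate 2 (0.1; 0.00143 to 0.529 over the alternatives). MBD3 lost it without any of the 4 normal libraries, CD4 replicate 1 (0.0757) or 2 (0.112) or CD8 replicate 1 (0.0794) or 2 (0.104), with 0.00248 to 0.476 over the alternatives. Depth divided the human libraries, with 1 CD4, 1 CD8 and 2 hPTCL libraries above 100 M reads. Of the 168 span genes called, 154 could be tested in the deep libraries alone, where 35 passed, and 167 in the others, where 24 passed. With depth class as a block 127 passed. Direction was kept by all 154, all 167 and all 168 in these settings. The same libraries gave the calls, so this is no independent check. Over all 3146 rows, whose names are not used, 584 were higher and 366 lower, 950 in all; the count was 514 without CD4 replicate 1, 516 without CD4 replicate 2 and 361 without CD8 replicate 2.

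**Figure D3:**
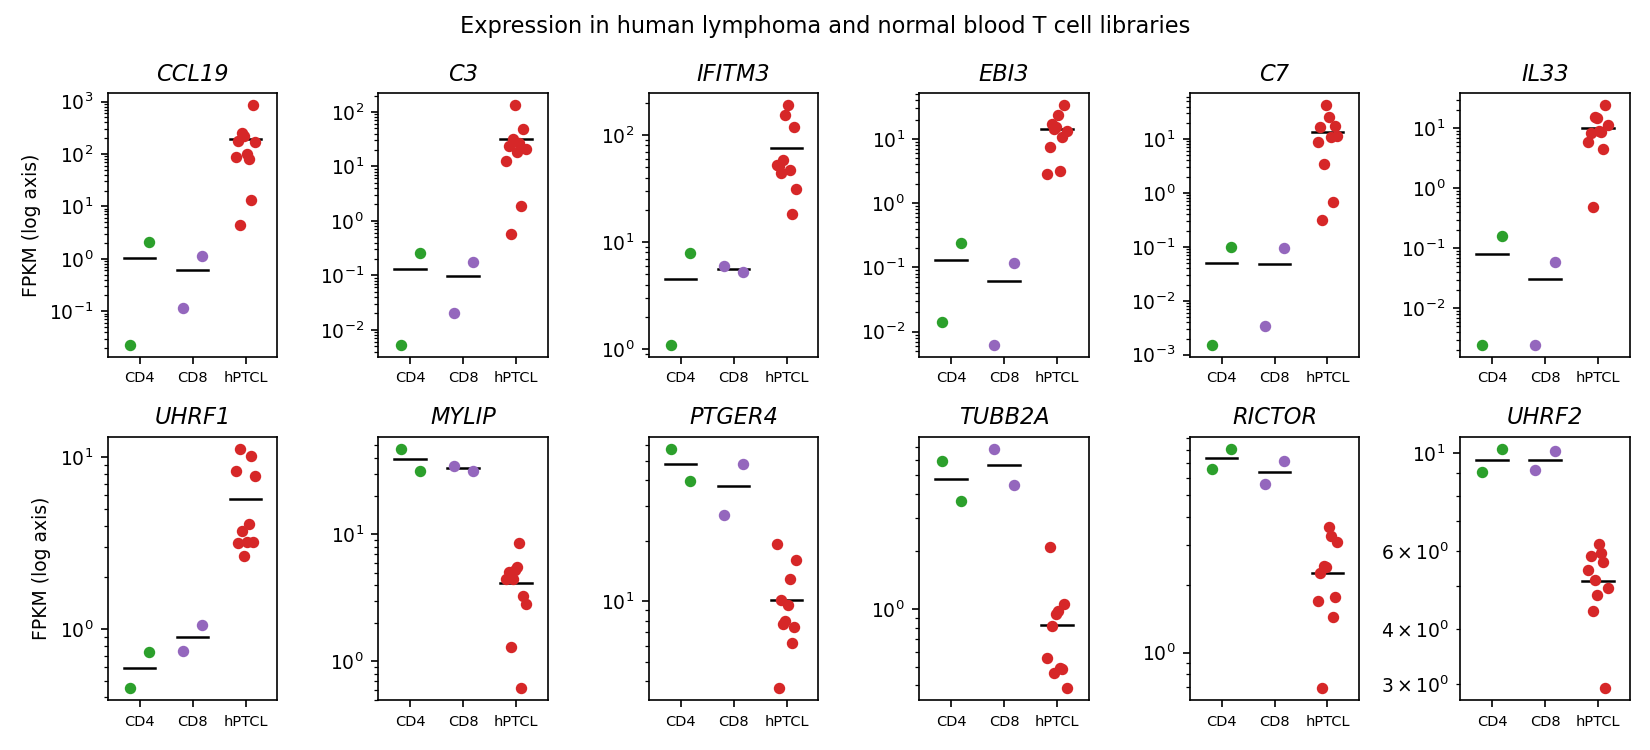
Expression of 12 span genes in each human library (points, FPKM on a log axis; black lines, group means) for normal CD4 and CD8 T cells and for peripheral T-cell lymphoma (hPTCL). The lymphoma libraries lie above the normal ones for the first 7 genes and below them for the last 5.

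CD8 and CD4 T cells from normal blood were compared as a measure of difference between normal subsets. The kinase MATK, which restrains receptor signalling, was at 16.1 ± 7.25 FPKM in CD8 (SD, n = 2) and 4.44 ± 3.19 FPKM in CD4 (SD, n = 2), a log2 fold change of 1.72 (SE 0.73). It did not pass in limma, and neither did ZNF622 and E2F3, also higher in CD8, nor SLC22A23, ADTRP and FASTKD3, which were lower. In limma 0 of 487 span genes passed, with 2 at an unadjusted p under 0.05, and 0 of 3146 rows, with 21. Over all rows 1 passed without CD8 replicate 1, and 6 passed with replicate numbers as a block.

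Mouse and human calls were set side by side by symbol to look for changes common to the species. Of the 312 span symbols tested in both, 94 were raised and 20 lowered in hPTCL, and 0 were among the mouse calls of either mutant in limma. No gene could therefore be shared, and a test of the overlap says nothing. Over all 1304 symbols, most with human values that are not read as those of the gene, the mouse calls were 0 as well. There, without D/D replicate 2 there was 1 symbol raised in both species, and without wild-type replicate 3 there was 1 lowered in both. At an unadjusted p under 0.05 the mouse comparisons had 433 genes for D/D and 721 for CI/CI.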

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

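The tests of reordered human values, of sequencing depth in the libraries numbered 4, of the animals' sex and of a linked stretch of chromosome, and the drawn splits for both mutants and for the human samples, were chosen after the result was seen.

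Gm4779 and 8030474K03Rik, 232 bp apart on the X chromosome, were the only 2 of 34244 genes with at least 5 FPKM in every CI/CI library and less than 0.5 FPKM in every other, and D/D and wild type had 0 such genes by this count, to which no test was applied. The sex of the animals is argued against, since 5 of the 6 other libraries and 4 of the 5 CI/CI libraries had the Y-linked Ddx3y above 1 FPKM, and a linked stretch of the altered allele's chromosome is argued against, since Dnmt3b lies on chromosome 2. A change of the whole region is argued against too: the 16 other tested genes within 1 Mb had a median log2 fold change of -0.13 (bootstrap -0.25 to 0.07), with 4 higher; the nearest, Cxcr3 at 55783 bp, was higher by 2.73 in CI/CI, but by 3.15 in D/D too, where the pair was off. An effect of the CI allele on these promoters may explain the pair, and so may a difference in genetic background between the CI/CI line and the other mice. Neither was tested here.

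Wild-type replicate 4 and CI/CI replicate 4 deviated together from their groups, with a Pearson r of 0.707 across 10198 genes. Gene length is argued against (Spearman rho -0.055), while sequencing depth stays open: the wild-type library, at 34.0 M reads, lies above the 30.8 M of another tumour, but both are the least deep of their genotype, and CI/CI replicate 4, at 28.4 M reads, has the most genes without reads (23087). The shared deviation followed GC content with a rho of 0.63 over the 80.2% of genes with a value, taken from human counterparts; singly the rho was 0.492 and 0.672, and -0.618 to 0.464 in the other libraries. A GC bias of these libraries is a candidate explanation, and a likeness of the tumours themselves was not tested. The 36 replication histone genes tested had a median deviation of 0.627 on the log2 scale, with 77.8% higher, and what this reflects was not tested either. Without both libraries 3 genes passed in limma for CI/CI against wild type, as with them, and 4 lists in place of 2, with MYC targets and JAK-STAT genes added.

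Human values outside the 6 spans did not follow the gene named in their row, with 14.8% of the tracers there in place. A reordering of rows or names is argued against, since it would leave the number of expressed genes as it was, while no human library had more than 3377 genes with at least 1 FPKM and no mouse library fewer than 9024. Reads placed on one genome build and counted over gene models of another may explain it: in 25 of 52 windows outside the spans odd and even tracers chose the same shift, against at most 7 in 1000 permutations. The notes name hg19, and the coordinates in the table are those of GRCh38. No biological explanation was tested.

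Single libraries lay far from the others of their group in 7 of 44 values tested, where chance sets apart about 1 in 20 groups. Dnmt3b stood at 8.51 FPKM in CI/CI replicate 4, with the next CI/CI library at 5.11. Myc stood at 1.34 FPKM in CI/CI replicate 1. Met stood at 0.271 FPKM in the same library. Cxcr3 stood at 8.14 FPKM in CI/CI replicate 5, below the other CI/CI tumours. In 1 hPTCL library IL33 was as low as 0.49 FPKM and FAM8A1 as low as 0.859 FPKM, and in another TUBB2A was as high as 2.11 FPKM.

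CI/CI and D/D tumours differed, by the test of one against the other, for 3 genes and 3 lists. By the splits given below, chance cannot be excluded for either count, and whether the differences come from the alleles was not tested. The difference was 5.29 for Gm4779, 4.50 for 8030474K03Rik and -4.17 for AI506816 on the log2 scale. The median difference was -0.20 for T-cell identity genes, -0.48 for cytotoxic genes and 1.74 for neutrophil genes (camera at the preset correlation; none of the lists passed with an estimated correlation).

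Other splits of the same libraries show how far chance reaches. For D/D against wild type, with 3 genes and 2 lists, there are only 10 splits, too few for a share under 0.05; 2 of them gave as many genes, with 104 as the highest of the others, and 9 gave as many lists, with 8 as the highest. The split with 104 genes set wild-type replicates 2 and 4 with D/D replicate 2 and points to a structure of the samples. Wild-type replicate 2 and D/D replicate 2 deviated alike from their groups (Pearson r 0.461 across genes). They also stood together on the second principal component, an axis holding 21.8% of the variance, at 43.39 and 45.9, with wild-type replicate 4 next at 17.03. The cause was not tested. For CI/CI against wild type 4 of 56 splits gave at least 3 genes and 38 gave at least 2 lists, so chance cannot be excluded for either count. The highest other splits gave 991 genes, with wild-type replicates 2 and 4 and CI/CI replicate 4 together, which again points to a structure of the samples, and 9 lists. Among the 8 splits that part all 3 numbered pairs, the real one gave 3 genes and the highest other 0, but 8 splits are too few for a share under 0.05.

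For CI/CI against D/D 3 of 56 splits gave at least 3 genes (highest other 4) and 32 gave at least 3 lists (highest other 8), so chance cannot be excluded for either. For genes changed alike in both mutants 4 of 100 drawn splits, the real one included, gave at least 1 gene. This is a share under 0.05 for draws that ignore the replicate numbers. The real count was only 1, and the highest other gave 22, which points to a structure of the samples. Chance is therefore not excluded for this count. For hPTCL against normal T cells 1 of 100 drawn splits, the real one, gave as many as 950 rows (highest other 152), and 1 of 100 gave as many as 168 span genes (highest other 40), so chance can be excluded for both; tissue of origin stays open.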

How the results depend on the processing

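The span genes, the depth classes, leaving out both libraries numbered 4, the replicate block with an estimated correlation and, for gene counts and named genes but not for lists, leaving out a library of the genotype not compared were chosen after the data were seen. Gm4779 and 8030474K03Rik passed in all 22 alternatives run in both CI/CI comparisons, and Trbj2-1 in all 22 in D/D (log2 fold change 5.83 to 7.24) and in CI/CI against wild type (4.78 to 6.40). Single named genes and lists kept direction and side of the threshold 2323 times, gained the call 104 times, lost it 88 times and reversed 23 times. These totals include many genes without a call, for which the same side means no call. Of the other D/D calls against wild type, AI506816 was kept in 14 of 22 alternatives and 2700081O15Rik in 8 of 21. Gene and list counts stayed within 1.5 times of their value 185 times and moved 89 times. Where a filter, a removed group or a removed library changes the number of genes or samples, that is part of the setting; otherwise the cause was not tested.

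In D/D against wild type, 3 genes became 1 with a pseudocount of 0.1 FPKM, 5 without a filter, 22 with arrayWeights and 7 in a fit of the 2 compared genotypes, and 1 to 58 when single libraries were left out. The 2 lists became 1 at a mean of at least 5 FPKM, 5 with arrayWeights, 4 with the replicate block, 0 with an estimated correlation (camera), 0 with fry, and 1 to 4 when single libraries were left out. In CI/CI against wild type, 3 genes became 5 without a filter, 7 with quantile normalization, 666 with arrayWeights, 21 with the replicate block and 29 in the fit of 2 genotypes, and 3 to 66 when single libraries were left out. The 2 lists became 4 without a filter, 5 at a mean of at least 5 FPKM, 4 without both libraries numbered 4, 1 with an estimated correlation, 1 with fry, and 2 to 6 when single libraries were left out.

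In CI/CI against D/D, 3 genes became 5 without a filter, 38 with arrayWeights, 12 with the replicate block and 18 in the fit of 2 genotypes, and 2 to 19 when single libraries were left out. The 3 lists became 1 at a mean of at least 5 FPKM, 5 with arrayWeights, 0 with an estimated correlation, 0 with fry, and 2 to 4 when single libraries were left out. With the replicate block and an estimated correlation together, 0 lists passed in camera in each of the 3 mouse comparisons. In CI/CI against wild type the block alone added the neutrophil list and changed no other list call. The 1 gene shared by both mutants became 3 without a filter, 17 with arrayWeights, 2 with the replicate block and 1 to 25 when single libraries were left out. Symbols raised in both species went from 0 to 19 with arrayWeights, and 0 to 1 when single libraries were left out; lowered symbols went from 0 to 5 and 0 to 1.

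For hPTCL against normal T cells, 950 of all human values tested became 2746 without a filter, 239 at a mean of at least 5 FPKM, 1523 with arrayWeights, 460 against CD4 alone, 333 against CD8 alone, 222 in libraries above 100 M reads and 305 below, and 361 to 687 when single normal libraries were left out. The 168 span genes became 91 at a mean of at least 5 FPKM, 272 with arrayWeights, 78 against CD4 alone, 59 against CD8 alone, 40 in libraries above 100 M reads and 24 below, and 74 to 115 when single normal libraries were left out. CD8 against CD4 went from 0 to 23 without a filter, 1 at a mean of at least 5 FPKM, 7 with arrayWeights, 6 with the replicate block, 4 in a fit of the 4 normal samples, and 0 to 1 when single libraries were left out, where a lone sample was assumed to vary like the other groups. Its span genes stayed at 0 in limma throughout.

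Direction reversed for genes whose difference was smaller than its standard error. For D/D against wild type, Dnmt3b was at -0.128 without D/D replicate 3 and Dnmt1 at -0.046 without D/D replicate 1. For CI/CI against wild type, Dnmt1 was at -0.003 without wild-type replicate 3, Dnmt3a at -0.046 without wild-type replicate 2, and Bax at 0.014 with the replicate block and 0.02 without wild-type replicate 2. Trp53 there was at 0.067 with arrayWeights, 0.088 with the replicate block, 0.217, 0.046 and 0.025 without wild-type replicate 4, CI/CI replicate 3 and CI/CI replicate 5, and 0.081 without both libraries numbered 4. For CI/CI against D/D, Dnmt1 was at 0.179, 0.094 and 0.142 without D/D replicate 1, D/D replicate 3 and CI/CI replicate 3, and Myc at 0.285 with arrayWeights. Gzma was at -1.034, -0.248, -0.246 and -0.06 without D/D replicate 2 and CI/CI replicates 1, 2 and 3, and Lck at 0.051, 0.027 and 0.035 without D/D replicate 1 and CI/CI replicates 1 and 5. Over single libraries left out, the opposite ends were 0.425 for Dnmt3b and 0.471 for Dnmt1 in D/D against wild type; 0.396 for Dnmt1, 0.36 for Dnmt3a, -0.407 for Bax and -0.224 for Trp53 in CI/CI against wild type; and -0.338 for Dnmt1, 1.237 for Gzma and -0.123 for Lck in CI/CI against D/D. The cause was not tested.

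Depth limits low genes: a gene without reads sits at 0.9 of a read, and human depth ran from 19.2 to 134.2 M reads.

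The planned settings for human lists, with each normal library left out, were not run, since 0 human lists had enough members.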

Other observations

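All values in this part were looked up after the data were seen, and no explanation was tested for them.

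T-cell receptor segments differed between single tumours. Trbv2 made up 87% of Trbv signal in wild-type replicate 2, Trbv16 98.2% in wild-type replicate 3, Trbv19 79.1% in wild-type replicate 4, Trbv13-1 99.2% in D/D replicate 1, Trbv14 92% in D/D replicate 2, Trbv19 94.8% in CI/CI replicate 4 and Trbv5 91.1% in CI/CI replicate 5. The Trbv sum was only 19.1 FPKM in wild-type replicate 2, 51.7 FPKM in wild-type replicate 4 and 87.6 FPKM in CI/CI replicate 4. In the other tumours just named it was 364 to 700 FPKM. The receptor segment Trdc stood at 42.1 FPKM in wild-type replicate 2 and at 2.06 FPKM or less in every other mouse library. In CI/CI replicates 1, 2 and 3 the leading Trbv segment held 37.4%, 39.3% and 46.7%, and in D/D replicate 3 it held 26.8% of a sum of only 3.07 FPKM.

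The X chromosome in CI/CI replicate 4 had a median deviation of -0.51 on the log2 scale from the median of the other mouse libraries, with 26.8% of 269 genes higher, and in wild-type replicate 4 a median of -0.32, with 27.9% higher; random gene sets of that size reached 0.169 and 0.165. Both libraries were shifted on other chromosomes too, less far. In CI/CI replicate 4 the median was -0.257 on chromosome 3 and 0.228 on chromosome 17. In wild-type replicate 4 it was -0.202 on chromosome 3 and 0.161 on chromosome 7. The deviations of both libraries across genes also followed GC content (Spearman rho 0.672 and 0.492), so the shift of the X chromosome does not stand alone. Chromosome 15 in D/D replicate 1 had a median of 0.47, with 89.8% of 402 genes higher. Chromosome 12 in D/D replicate 2 had a median of 0.30, with 80.2% of its genes higher. Also raised were chromosome 3 in D/D replicate 1 (0.29, 85% higher) and chromosomes 6 (0.24, 78.9%) and 17 (0.21, 73.2%) in D/D replicate 2. Chromosome 7 in D/D replicate 1 was lower (-0.12, 34.2% higher).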
